A study of Sus scrofa with 3 samples.

How the data were processed

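Peripheral blood monocytes of 1 pig, obtained by adherence of mononuclear cells, were kept in medium for 4 h, exposed for 4 h to the probiotic bacterium Bifidobacterium animalis ssp. lactis Bb12 at 100 bacteria per cell, or given an antibody against Toll-like receptor 2 (TLR2) at 40 µg/mL for 1 h before the same bacteria. Per the labels, 1 µg of total RNA was labelled per condition and hybridized to a single-colour Cy3 microRNA array at a service provider. The series has 1 array for each of the 3 conditions. Its stated array replicates are 8 repeat spots of each miRNA probe on 1 array. The spread between repeat spots is a technical spread within an array, and array and condition cannot be told apart.

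The deposited spot values are intensities from a GenePix scanner, with scanner gains of 370, 390 and 360 for the unstimulated, Bb12 and anti-TLR2 + Bb12 arrays and no normalization between arrays, per the file headers. The background-corrected sheet equals a spatially flattened density minus 1 background level per array, with lower values set to 0.01 intensity units. The method of the flattening is not given in the sources used here. The deposited summary gives each probe's mean intensity over the spots its provider kept. For 454 of 454 summarised probes on each array, exactly 1 subset of the spots, of the stated size, gave that mean, which identified the outlier spots. The deposited summary also gives a p-value of signal against background for each probe, with no method stated in the sources used here. A value table for the whole series holds linear intensities that the authors or their provider scaled between arrays. The scale is linear and uncentred, and the scaling method stays unknown. Its column medians were 17.1, 16.3 and 18.2 intensity units in the order above, and its values were 1.02, 0.725 and 1.33 times the summary means (medians over miRNAs detected on all arrays).

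Pig miRNA probes (407) were used and control spots were left out. Of 3256 miRNA spots per array, 3192, 3148 and 3235 were kept in the same order after removal of outlier spots. Spot intensities were quantile-normalized across the 3 arrays with limma 3.58.1 in R 4.3.3, set to at least the detection limit of the array carried to the normalized scale, log2-transformed and averaged over a probe's repeat spots. The detection limit was 3 times the background SD, which was 17.9, 26.9 and 9.88 intensity units before normalization. The floors after normalization were 4.24, 4.36 and 3.76 log2 units. A miRNA was detected where a share of at least 0.5 of its spots exceeded the limit, since the files hold no detection flag. Other steps used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9.

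Each of the 3 comparisons set 1 array against another. No test across samples was possible, and no p-value is given. A miRNA was called different when its log2 difference was at least 1 in size, it was detected on at least 1 of the 2 arrays, and all its spots on 1 array lay above all its spots on the other. Where the dimmer array did not detect it, the fold is given as a lower bound under this processing. The bound is the brighter array's mean against the higher of the lowest mean among miRNAs detected on the dim array and the probe's own mean there. Errors are the SD or SE between repeat spots. For 12 miRNA lists, the median log2 difference of the detected members was placed among 10000 random lists of the same size, matched on mean signal in 10 bins. Lists with under 3 detected members were given no percentile. A percentile describes these arrays and is not a test between conditions.

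The comparisons, the call rule, the lists and most alternatives were fixed before the data were examined. The rule for named miRNAs took the 10 largest called rises and falls per comparison among miRNAs detected on both arrays and the 5 largest bounds in each direction. It also took every detected member of the TLR and NF-kB response list and the brightest 2 to 4 members of each other list. Other miRNAs named in the text were chosen after their values were seen. Names are those of the array files. The files name no genome build, so no positions are given. Gene neighbourhood was taken from RefSeq genes of assembly Sscrofa11.1, in which 158 of the 170 miRNAs detected on all arrays had a gene.

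The procedure was tested on 20 simulated series for Bb12 against unstimulated, each with 407 miRNAs and spot spreads taken from the arrays. Of 2898 results for unchanged miRNAs, 0 were called. Calls in the right direction were made for 0.625% of miRNAs changed 1.5-fold, 33.3% changed 2-fold, 93.1% changed 3-fold and 93.8% changed 4-fold. Of 20 lists of 8 miRNAs raised by 0.4 log2 units, 19 lay above the percentile of 97.5. These simulations hold spot noise and no difference between arrays other than scale.

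Alternatives were scaling on a median, cyclic loess, no normalization, the deposited series table, the deposited summary mean, normexp background correction with an offset of 50, other filters on dim miRNAs (detected on all arrays, none, or at least 500 intensity units), the median of the spots, odd or even repeats, a 1.5-fold size and the size rule alone. The normexp correction ran on raw spot density, because no local background per spot is among the values used here. Alternatives added after the data were seen were keeping the outlier spots, a common floor, detection at a deposited p-value under 0.01, and leaving out miRNAs that have a brighter near-identical relative. Such a relative has at most 3 base differences and is at least 4 times brighter on the mean of the unstimulated and Bb12 arrays.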

Results

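MicroRNA signals were measured in pig blood monocytes that were left unstimulated, exposed to the probiotic Bb12, or exposed to Bb12 after an antibody against TLR2, a receptor for bacterial lipoproteins. There was 1 array per condition and 1 animal, so no difference between conditions has a replicate check. Of 407 pig miRNA probes, 180 were detected on the unstimulated array, 184 on the Bb12 array and 204 on the anti-TLR2 + Bb12 array. The detection limits were 17.9, 26.9 and 9.88 intensity units in that order, lowest on the array with the highest count. These counts therefore do not show that the cells of 1 condition held more miRNAs. In all, 170 were detected on the 3 arrays and 196 on none. The median background-corrected intensity of the 170 was 422, 678 and 361 units in that order, before the arrays were brought to a common scale. The number of arrays limits the precision of every difference, and the errors below are spreads between repeat spots of a single array.

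The first comparison addressed how the monocytes' miRNAs differed after 4 h with Bb12. On the Bb12 array 6 miRNAs were higher than on the unstimulated array and 0 were lower, of 194 detected on at least 1 of the 2. The largest difference measured on both arrays was that of miR-574 (CACGCUCAUGCACACACCCACA), with a log2 signal of 8.93 ± 0.12 (SD, 7 spots) against 7.15 ± 0.37 (SD, 8 spots), or 3.43-fold. miR-9813-5p (CGGAAGGUCGGAGGAUGUGC) was 2.78-fold higher, at 6.63 ± 0.17 against 5.15 ± 0.38 (SD, 8 spots each). miR-31 (AGGCAAGAUGCUGGCAUAGCUG) was 2.06-fold higher, at 5.61 ± 0.15 against 4.57 ± 0.25. Another 3 were not detected on the unstimulated array, and their folds are bounds under this processing that some other settings did not reach. These 3 were miR-885-5p (UCCAUUACACUACCCUGCCUCU), at least 5.79-fold higher with Bb12, miR-99b (CACCCGUAGAACCGACCUUGCG), at least 3.16-fold higher, and miR-7138-5p (UCCCAGCAAGUGUCCAUCCAUCU), at least 2.05-fold higher.

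Most miRNAs differed little between these arrays. Of 170 detected on both, 156 (91.8%) lay within 1.5-fold. With the brighter array required to reach 500 normalized intensity units 0 were higher, and the brightest of the 6, miR-574, had 486. Scaling the arrays on a median gave 4 higher and 1 lower, the deposited series values 6 and 1, no normalization 17 and 0, and normexp background correction 2 and 0. miR-182, of the erythroid and platelet list, had a log2 difference of -0.90 and was called lower under the deposited series table, at -1.05. With outlier spots kept, miR-574 and miR-885-5p were no longer called. With normexp, miR-31 (0.40), miR-7138-5p (0.45), miR-9813-5p (0.72) and miR-99b (0.97) were not called, and the log2 difference of miR-885-5p was 1.40.

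The second comparison addressed whether an antibody against TLR2 altered the profile seen with Bb12. No array had the antibody without bacteria or a control antibody. A block of TLR2 therefore cannot be told apart from other effects of the antibody. With the antibody, 1 miRNA was higher than with Bb12 alone and 3 were lower, of 208. let-7e (UGAGGUAGGAGGUUGUAUAGUU), a member of the let-7 family, was 2.47-fold higher, at 9.41 ± 0.27 against 8.11 ± 0.30 (SD, 8 spots each). miR-345-3p (CCCUGAACUAGGGGUCUGGAG) was 2.16-fold lower, at 10.17 ± 0.18 against 11.28 ± 0.09 (SD, 8 spots each). miR-885-5p and miR-99b were not detected with the antibody, which put them at least 7.31-fold and 4.55-fold lower by the bound rule. Over the 18 other settings their log2 differences ranged from -3.15 to -1.13 and from -2.69 to -0.80, so these folds are not firm lower bounds. Of 180 miRNAs detected on both arrays, 147 (81.7%) lay within 1.5-fold.

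These arrays also differed in their controls. In 15 pairs of control probes measured on all 3 arrays, the probe named as a mismatch was set against its perfect-match partner. From the Bb12 to the anti-TLR2 + Bb12 array its relative signal rose by a median of 0.98 log2 units, with a range of -0.03 to 4.60. Many of these pairs share a perfect-match probe with another pair. A further pair, measured on the Bb12 and anti-TLR2 + Bb12 arrays only, changed by -0.83. The probe for let-7e has 1 base difference from that of let-7a, which had a brighter signal. Without normalization 0 miRNAs were higher and 82 lower, on a shift of all miRNAs of -0.88 log2 units, while 7 were higher and 4 lower with outlier spots kept, and 5 and 4 with odd repeats. With normexp the log2 difference of miR-885-5p was -1.13, and miR-99b, at -0.80, was not called.

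**Figure D1:**
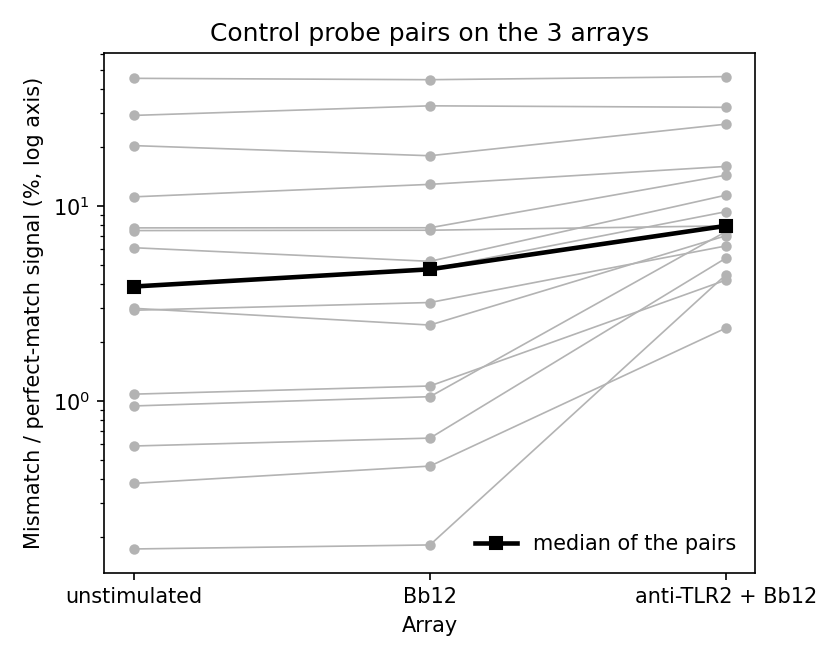
Mismatch signal as a percent of perfect-match signal (logarithmic vertical axis) for 15 control probe pairs on the 3 arrays, with grey lines for the pairs and a black line for their median. The median was 3.87% on the unstimulated, 4.74% on the Bb12 and 7.91% on the anti-TLR2 + Bb12 array.

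The third comparison set the antibody-treated, Bb12-exposed cells against unstimulated cells. Here 4 miRNAs were higher and 2 lower, of 207. miR-574 was 6.17-fold higher, at 9.77 ± 0.17 against 7.15 ± 0.37 (SD, 8 spots each). The others that were higher were let-7e (2.27-fold), miR-30c-3p (CUGGGAGAAGGCUGUUUACUCU, 2.11-fold, at 9.86 ± 0.16 against 8.78 ± 0.41) and miR-9813-5p (2.10-fold). miR-4335 (GUGCCCAGCGCUGCAGGGCA) and miR-331-5p (UCUAGGUAUGGUCCCAGGGAU) were not detected with the antibody and were 2.10-fold and 2.00-fold lower by the bound rule. Their unstimulated signals lay near the floor of 4.24, at 4.91 ± 0.82 and 4.84 ± 0.76 (SD, 8 spots each). Over the 18 other settings their log2 differences ranged from -1.44 to -0.51 and from -1.26 to -0.33, so these folds are not firm lower bounds. Neither was called with a floor common to the 3 arrays. The mismatch-to-perfect-match ratio of the controls was higher by a median of 1.09 log2 units on the anti-TLR2 + Bb12 array than on the unstimulated array. Of 177 miRNAs detected on both arrays, 148 (83.6%) lay within 1.5-fold. Scaling on a median gave 3 higher and 7 lower, the deposited series values 4 and 1, and no normalization 1 and 16.

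Of the 6 miRNAs higher with Bb12, 2 were also above unstimulated by at least 1 log2 unit in the presence of the antibody. Both differences use the same unstimulated array, so a low reading there would raise both. miR-574 had differences of 1.78 without the antibody and 2.63 with it, and miR-9813-5p had 1.48 and 1.07. miR-31 was on the same side with 0.76, under the size of a call. miR-7138-5p was detected with the antibody and not on the unstimulated array, so the size of its difference stays open. miR-885-5p and miR-99b were below detection both without bacteria and with the antibody. With the antibody, miR-9813-5p was not called under 7 of 18 other settings. These were median scaling (0.95), cyclic loess (0.93), no normalization (0.95), the deposited series table (0.89), the summary mean (0.94), normexp (0.51) and the filter at 500 intensity units, with the shift of all miRNAs taken off for median scaling, no normalization and the summary mean.

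**Figure D2:**
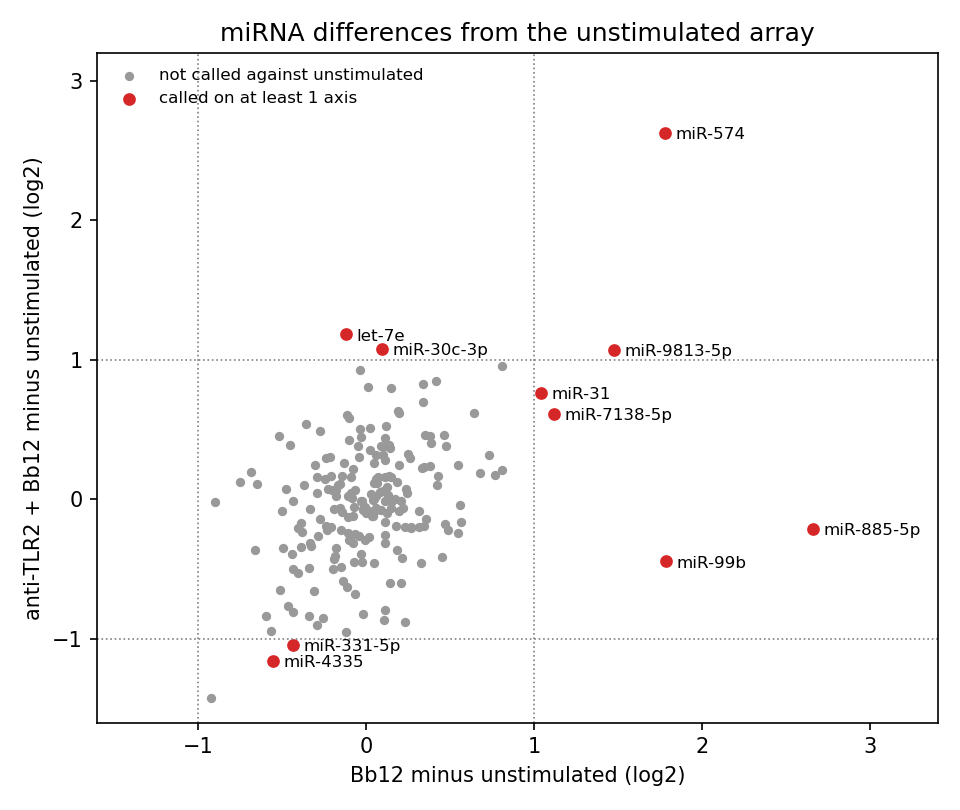
Log2 difference of each miRNA from the unstimulated array on the Bb12 array (horizontal axis) and on the anti-TLR2 + Bb12 array (vertical axis), for the 211 miRNAs detected on at least 1 array. Red points were called on at least 1 axis and dotted lines mark 1 log2 unit. miR-574 lies at 1.78 and 2.63, while miR-885-5p and miR-99b, drawn at 2.66 and 1.79 with undetected unstimulated signals at the floor, lie below 0 on the vertical axis. Neither array of the vertical axis detected them, so that position depends on the floors of both arrays.

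Across the 170 miRNAs detected on all arrays, the differences of the Bb12 and the anti-TLR2 + Bb12 array from unstimulated had a Pearson correlation of 0.464 across miRNAs, which are not independent replicates. The shared unstimulated array gave 0.686 in simulations with spot noise and no effect. The covariance was 0.0775, against 0.0101 in the simulations. The difference with Bb12 and the difference added by the antibody correlated at -0.368, against -0.433 simulated, with covariances of -0.0585 and -0.00514. The spot noise of the simulations leaves out variation between arrays, so part or all of the excess covariance may come from the shared array.

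Of 22 miRNAs known from Toll-like receptor and NF-kB responses, 20 were on the array. In Bb12 against unstimulated 15 were detected and 1 was called, miR-99b (higher). For the antibody against Bb12 15 were detected and both let-7e (higher) and miR-99b (lower) were called, and against unstimulated 14 were detected and let-7e (higher) was called. The NF-kB-inducible miR-155-5p had log2 signals of 11.04 ± 0.16, 11.18 ± 0.12 and 11.40 ± 0.08 on the unstimulated, Bb12 and anti-TLR2 + Bb12 arrays. miR-146a-5p, a feedback regulator of TLR signalling, had 13.02 ± 0.19, 13.06 ± 0.08 and 12.90 ± 0.08. miR-132 stood at 8.14 ± 0.34, 8.14 ± 0.31 and 8.04 ± 0.07, and miR-21 at 13.83 ± 0.12, 13.73 ± 0.06 and 13.54 ± 0.05. miR-146b had 10.19 ± 0.25, 10.09 ± 0.26 and 10.78 ± 0.16, and its probe has 3 base differences from that of the brighter miR-146a-5p. miR-212, miR-9, miR-149, miR-145-5p and miR-199a-5p were below detection on all 3 arrays. The median difference of the list was -0.10 with Bb12 (percentile 12.4 among random lists), -0.10 with the antibody against Bb12 (22.4) and 0.00 with the antibody against unstimulated (50.5). Over the other settings, leaving out the one with no filter, these ranged from -0.10 to 0.040, from -0.10 to 0.049 and from -0.09 to 0.11.

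**Figure D3:**
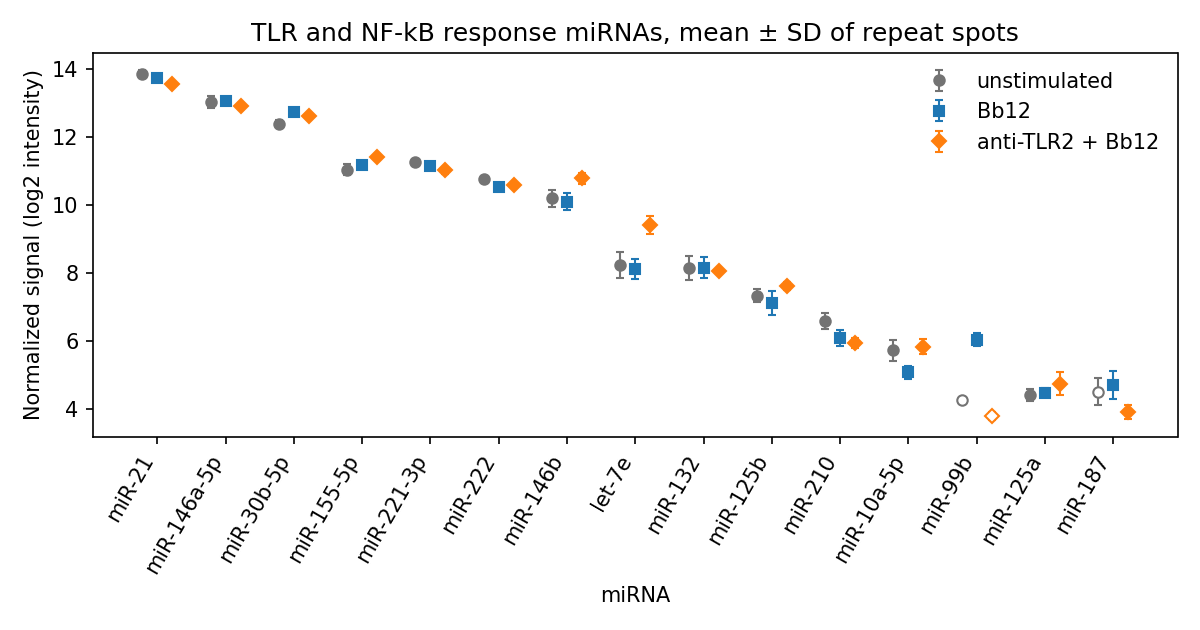
Normalized log2 signal of the 15 members of the TLR and NF-kB response list detected on at least 1 array, on each of the 3 arrays. Symbols are means and bars SDs of 6 to 8 repeat spots, and open symbols were below detection. miR-155-5p lay between 11.04 and 11.40 and miR-146a-5p between 12.90 and 13.06, while miR-99b was above detection on the Bb12 array alone and let-7e reached 9.41 with the antibody.

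The 8 detected members of the let-7 family had, on the antibody-treated array, a median difference of 0.31 against Bb12 (percentile 99.3) and 0.30 against unstimulated (99.7), with 7 of 8 above 0 in each. 1 member, let-7e, was called. In Bb12 against unstimulated the family had a median of -0.06 (27.8). Members with a near-identical relative at least 4 times brighter were then left out, a choice made after the values were seen. The 5 remaining had medians of 0.27 against Bb12 (96.2) and 0.11 against unstimulated (79.3), both inside the middle 95% of random lists. They still held let-7a, at 11.66 on the unstimulated array, whose probe has 1 base difference from that of let-7f, at 13.07. The mismatch-to-perfect-match ratio of the controls was higher on the same array, by medians of 0.98 and 1.09 log2 units. The miR-30 family had a median of 0.31 with Bb12 (percentile 99.4), with 5 of 5 members above 0 and 0 called. Its probes are close in sequence and may share signal, which the random lists, matched on signal alone, do not take into account. miR-30b-5p was at 12.72 ± 0.08 against 12.39 ± 0.10 and miR-30e-5p at 12.75 ± 0.06 against 12.43 ± 0.12. With the antibody the family's medians were -0.10 against Bb12 (28.6) and 0.12 against unstimulated (94.7), and the first turned to 0.08 with median scaling. The miR-181 family had medians of 0.07 with Bb12 (69.1), -0.37 for the antibody against Bb12 (2.25) and -0.29 for the antibody against unstimulated (4.36), with 0 called.

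The other families and clusters had 0 called members in the 3 comparisons. In the order Bb12 against unstimulated, antibody against Bb12 and antibody against unstimulated, the medians of the miR-17-92 clusters were -0.11, -0.04 and -0.06 (percentiles 5.67, 43.5 and 27.1). Those of the miR-15/16 family were 0.22, -0.14 and -0.01 (94.1, 25.3 and 62.2). The miR-23/27/24 clusters had -0.09, 0.15 and 0.01 (26.3, 82.1 and 59.0), and the miR-29 family -0.33, 0.02 and -0.31 (3.73, 60.9 and 6.74). Several of these medians turned in sign over the same settings. The miR-15/16 medians ranged from -0.10 to 0.25, from -0.23 to 0.17 and from -0.039 to 0.20, and the miR-17-92 medians reached 0.14 for the antibody against Bb12 and 0.0048 against unstimulated. For miR-23/27/24 the first reached 0.0052 and the third -0.041, and for miR-29 the second reached -0.084.

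Markers of other cells were read alongside. Of the 11 myeloid miRNAs, 9 were on the array, with no probe matched to miR-223-3p or miR-223-5p. Among the 9 was miR-142-5p at 12.80 ± 0.06, 12.51 ± 0.23 and 12.85 ± 0.27. miR-21 and miR-146a-5p stand in this list and in the TLR list. The myeloid medians were -0.09, -0.05 and -0.12 (percentiles 18.4, 51.0 and 10.5), with 0 called, and the second was above 0 in 11 of 12 other settings, reaching 0.23. The lymphocyte list had 9 of 9 members detected. Its miR-150, which is abundant in mature lymphocytes, was at 13.63 ± 0.08, 13.46 ± 0.04 and 13.74 ± 0.06. Its medians were -0.11, 0.02 and 0.03 (14.3, 60.1 and 58.0), and miR-31 was its called member. For the antibody against Bb12 the median was below 0 in 5 of 12 other settings and against unstimulated in 4, with a lowest of -0.21 in each. Of 8 erythroid and platelet miRNAs 3 were detected, with miR-451 at 6.14 ± 0.36, 6.37 ± 0.27 and 5.94 ± 0.22 and list medians of -0.33, -0.00 and -0.20 (8.73, 41.6 and 15.2). The second reached 0.19 with outlier spots kept. Of 9 measured miRNAs typical of tissues outside the blood, miR-499-5p was detected on all 3 arrays, at 6.05 ± 0.16, 5.87 ± 0.17 and 6.11 ± 0.15, and miR-206 on the Bb12 array alone, at 4.51 ± 0.26. With so few members detected, no list difference is given.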

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

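The tests in this part were chosen after the result was seen. The control probes, which no comparison used, carried a signal that differed between the arrays. Of 27 pairs of a mismatch and a perfect-match probe, as read from their names, 15 were measured on all arrays. Many of the 15 share a perfect-match probe with another pair, so the pairs are not all independent. From the unstimulated to the anti-TLR2 + Bb12 array the mismatch-to-perfect-match ratio was higher in 15 of 15 pairs, with a median change per pair of 2.14-fold and a highest of 25.4-fold. Between the unstimulated and Bb12 arrays the median log2 change was 0.13, with 11 of 15 pairs up.

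A set of 9 miRNAs had a relative with at most 3 base differences that was at least 4 times brighter. Brightness was the mean of the unstimulated and Bb12 arrays. The set holds 3 of the let-7 family and was defined after its differences were seen. Of the 9, 8 were higher on the anti-TLR2 + Bb12 array than on the Bb12 array. Their median difference was 0.49 (percentile 99.8 among random lists), against -0.07 for their brighter relatives, and let-7e was the highest at 1.30. Choosing miRNAs dimmer than a relative on the Bb12 array can itself raise their difference and lower that of the relatives. The random lists were not chosen in this way, so the percentile does not take this into account. With a linear GC trend removed the median was 0.44, above the random range that ended at 0.35. That trend was weak over all miRNAs (Spearman correlation -0.14), so its removal could move the median little. A linear GC trend thus accounts for little of the difference, and other effects of base content were not tested. Less specific hybridization on the anti-TLR2 + Bb12 array is a candidate explanation, because the control ratio rose by 0.98 log2 units against the Bb12 array. The 6 members outside the let-7 family had a median of 0.39 (percentile 96.8), inside the middle 95% of random lists, and an effect of the antibody on these miRNAs cannot be told apart from this with 1 antibody-treated sample.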

How the results depend on the processing

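No paired analysis was possible because each condition had 1 array. Signal over background limits the calls of dim miRNAs, whose size depends on the floor and the background correction. Without normalization the median of miRNAs detected on all arrays shifted by 0.45 log2 units for Bb12 against unstimulated, -0.88 for the antibody against Bb12 and -0.39 for the antibody against unstimulated. With the summary mean these were 0.43, -0.89 and -0.41, and with median scaling -0.24, 0.03 and -0.16. Medians of lists, values of single miRNAs and the number of settings in which each call held are given relative to shifts over 0.1, while counts are as called. Keeping outlier spots, the common floor, the deposited p-value and leaving out miRNAs with a brighter relative were chosen after seeing the data. With the 1.5-fold size, the size rule alone and no filter, looser rules met the same values, so no call could be lost there. Of the calls, miR-345-3p (antibody against Bb12, -1.18 to -1.05) and miR-574 (antibody against unstimulated, 2.14 to 2.69) held under 18 of 18 settings. let-7e held in 17 for both antibody comparisons, miR-30c-3p in 17, miR-9813-5p against unstimulated in 16 without and 11 with the antibody, and miR-4335 and miR-331-5p in 10. With Bb12 against unstimulated, miR-574 held in 16 (1.20 to 1.89), miR-885-5p in 15 (1.40 to 2.74), miR-99b in 15 (0.97 to 1.98), miR-31 in 15 (0.40 to 1.17) and miR-7138-5p in 14 (0.45 to 1.30). For the antibody against Bb12, miR-885-5p held in 16 (-3.15 to -1.13) and miR-99b in 15 (-2.69 to -0.80). With the shifts left in, as in the counts, let-7e (both comparisons) and miR-30c-3p held in 15, being lost without normalization and with the summary mean too, and miR-31 held in 14 and miR-7138-5p in 13, both lost with median scaling too, while the other calls held in the same number. No called value changed direction. Among the values of named miRNAs, 22 fell under the threshold, 5 passed it and 1377 kept their side. Most of the 1377 are of miRNAs that were not called, which could not fall under it. Of the list medians 395 moved by less than the median spot SD of their members, combined over the 2 arrays, and 28 did not. That SD is of single miRNAs and not of a list median, so a median could turn in sign and still be among the 395. Of the counts 77 stayed within 1.5 times and 51 did not. For the values that follow the cause was not tested, except that stricter filters leave fewer miRNAs, a smaller size admits more, and with no filter undetected members enter at the array floors.

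With median scaling, 1 miRNA was lower in Bb12 against unstimulated, 2 were higher for the antibody against Bb12, 7 were lower for the antibody against unstimulated, and 1 Bb12 difference was kept. The antibody against Bb12 then gave medians of 0.23 for the myeloid list, 0.51 for let-7, 0.14 for miR-17-92, 0.050 for miR-15/16 and 0.082 for miR-30. Cyclic loess gave 2 higher for the antibody against Bb12 and 1 kept. Without normalization 17 were higher with Bb12, 0 higher and 82 lower for the antibody against Bb12, 1 higher and 16 lower for the antibody against unstimulated, and 1 kept, with myeloid 0.21 and miR-30 0.054 for the antibody against Bb12. The summary mean gave 17, 0 and 83, 1 and 15, and 1 in the same order, with myeloid 0.21, miR-17-92 0.12 and miR-30 0.059. The deposited series table gave 1 lower with Bb12, 2 higher for the antibody against Bb12, 1 lower for the antibody against unstimulated, 1 kept, and an erythroid and platelet median of -0.45 for the antibody against unstimulated. Normexp gave 2 higher with Bb12, 0 lower for the antibody against unstimulated, 1 kept, and 0.060 for miR-15/16 in the antibody against Bb12.

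Among miRNAs detected on all arrays, 3 were higher with Bb12, 1 was lower for the antibody against Bb12 and 0 were lower for the antibody against unstimulated, with a miR-15/16 median of 0.0070 for the antibody against Bb12. With no filter, the erythroid and platelet medians were those of 5 members below detection on all arrays and equal the gaps between floors, 0.11 with Bb12, -0.60 for the antibody against Bb12 and -0.49 for the antibody against unstimulated, miR-15/16 had -0.28 for the antibody against Bb12, and the TLR list -0.22 for the antibody against unstimulated. At 500 intensity units 0 were higher with Bb12, 1 was lower for the antibody against Bb12, 0 were lower for the antibody against unstimulated and 0 were kept. The miR-15/16 medians were then 0.032 with Bb12 and 0.0070 for the antibody against Bb12, and the lymphocyte median -0.19 for the antibody against unstimulated. The median of the spots gave 1 lower with Bb12, 2 higher for the antibody against Bb12 and 0 lower for the antibody against unstimulated, odd repeats gave 1, 5 and 4, and even repeats 2 higher for the antibody against Bb12. A 1.5-fold size gave 4 lower with Bb12, 14 higher and 16 lower for the antibody against Bb12, and 11 higher and 11 lower for the antibody against unstimulated.

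With outlier spots kept, 1 was lower with Bb12, 7 were higher for the antibody against Bb12, 1 was lower for the antibody against unstimulated and 1 was kept. The miR-15/16 median was then -0.10 with Bb12. For the antibody against Bb12, myeloid had 0.11, lymphocyte -0.21 and miR-23/27/24 0.46, and lymphocyte had -0.21 for the antibody against unstimulated. A common floor left 0 lower for the antibody against unstimulated, as did the deposited p-value, which gave miR-15/16 medians of 0.17 for the antibody against Bb12 and 0.20 for the antibody against unstimulated. Without miRNAs that have a brighter relative, 0 were higher for the antibody against Bb12.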

Other observations

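The tests on miR-885-5p, miR-99b and the miR-99b cluster were chosen after the result was seen, and the test of neighbouring genes before. The miR-99b, let-7e and miR-125a genes are neighbours, with let-7e 90 and miR-125a 566 bases from miR-99b in RefSeq genes of Sscrofa11.1. With Bb12, miR-99b was at least 3.16-fold higher by the bound rule than on the unstimulated array, which did not detect it. The log2 differences of let-7e and miR-125a were -0.12 and 0.061. These values do not decide whether shared transcription raised miR-99b. miR-125a lay near the floor, at 4.41 and 4.47 log2 units against floors of 4.24 and 4.36, and the probe of let-7e has a brighter near-identical relative, let-7a.

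Neighbouring genes were then tested as a set, on the hypothesis that real changes in transcription would make miRNAs encoded within 10000 bases differ alike. There were 66 such pairs, made from 54 miRNAs, without arms of the same hairpin or pairs with at most 4 base differences. For the antibody against Bb12 the median gap between partners was 0.48 log2 units, wider than in most random sets (percentile 99.3 of 10000). This argues against shared transcription as the main source of those differences. It does not exclude a smaller shared part, because the control ratio also differed between these arrays, by a median of 0.98 log2 units. Pairs were chosen by distance, and strand was not used. For Bb12 against unstimulated the gap was 0.24 (percentile 30.6) and for the antibody against unstimulated 0.24 (12.7). The bound set beforehand against the hypothesis was any percentile from the fifth up, which both values meet. That bound was too strict to exclude it, because both gaps lay below the random medians of 0.26 and 0.31, on the side that the hypothesis predicts and inside the random spread, so it stays open there. Random sets were first drawn as independent pairs (30.9, 99.9 and 10.2) and then, after those were seen, by shuffling miRNAs so that pairs kept their shared members.

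miR-885-5p and miR-99b were above detection on the Bb12 array alone, with used spots between 144 and 173 and between 79.3 and 109 intensity units. A higher overall sensitivity of the Bb12 array is argued against by the other miRNAs, whose unnormalized log2 difference from unstimulated had a median of 0.43 (SD 0.39), while the pair had at least 2.36. Light spilling from bright neighbours is argued against by 611 spots of other miRNAs undetected on the other two arrays that lay beside a spot of at least 1000 units, with a median of 0.072 and a highest value of 44.7 units. Of the 7 used spots of miR-99b, 5 had no such neighbour and lay between 81.8 and 109 units, while those of miR-885-5p all had one. A rise in the cells with Bb12 and a fault of 1 chip cannot be told apart, because 1 Bb12-treated sample without antibody was measured.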
